A study of Homo sapiens with 12 samples.

How the data were processed

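RNA from HCT116 cells treated with dolastatin 15 (20 nM or 100 nM) or solvent for 16 h or 24 h was measured by RNA sequencing in 12 libraries, 2 for each of 6 groups. Per the labels' protocols, cells grown in DMEM with 10% serum were seeded in 6-well plates in medium with 5% serum, DMSO was kept at 0.25%, and treatments were made in duplicate. RNA was purified with a Qiagen kit, RNA integrity numbers were at least 7, and 1000 ng of total RNA per sample went through poly(A) selection and a directional NEBNext library kit, per the labels' protocols. The 12 libraries were pooled in equal amounts and sequenced on an Illumina HiSeq instrument in 2 runs of paired reads with 100 cycles per end, per the labels' protocols. Poly(A) selection captures transcripts without a poly(A) tail poorly, among them most replication-dependent histone mRNA and many small RNAs, so their levels depend on that step.

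The authors deposited 1 table of FPKM (fragments scaled to transcript length and to the mapped fragments of the library) per gene and library, rounded to 2 decimals, with 58174 genes. RSEM 1.2.28 and the GRCh38 build are named in the submitters' processing notes. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes, and near-identical copies among which RSEM divides reads, are uncertain. FPKM keeps no read counts, and a search for steps of whole reads among low values (the smallest above 0 is 0.01 in each library) gave no depth, so no counting interval or floor could be set and precision rests on the spread between libraries. A value of 0 may be a failed estimate, so a named gene with a library at 0 in a group compared is given without a fold, while list medians and tests use the fitted values.

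The columns name the group and a library number but not the sample number of the labels, so libraries entered as members of their group without pairing. GENCODE 29 on GRCh38 gave symbols, gene types, lengths and positions for 57836 genes by identifier, and 338 had no symbol. About 1% of tested values were identical between libraries of a group, so no library was taken for a copy of another. The first 3 principal components held 25.9%, 23.7% and 11.0% of the variance.

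Genes with FPKM of at least 1 in at least 2 of 12 libraries were tested (13458, of which 11660 protein-coding). Values were log2(FPKM + 1), so log2 changes understate the change of low genes. limma 3.58.1 in R 4.3.3 fitted 6 group means with a mean-dependent prior to all libraries (6 residual and 2.98 prior degrees of freedom), and tests of 9 contrasts were two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were each dose against solvent at each time, dose against dose, solvent at 24 h against 16 h, and the difference of each dose's effect between times. A simulation of 100 nM against solvent at 24 h had 13458 genes and 5 draws. The fit recovered 39.2% of 1.25-fold, 83.6% of 1.5-fold, 98.4% of 2-fold and 99.2% of 4-fold changes, and 5.54% of calls were false. These rates hold for the simulated noise and changed genes and may differ for low genes.

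The comparisons, the test, 33 gene lists (745 symbols, 744 of them found) and the rule for named genes were fixed before the data were examined. The rule took, for each drug comparison, the 10 largest increases and 10 largest decreases among called genes with a symbol, both treated libraries beyond both solvent libraries and a higher group mean of at least 2 FPKM. It took 5 and 5 for the other comparisons, and the 5 and 5 called in all 4 drug comparisons with the largest smallest change. Members of the lists could be named as well, and those shown as examples were chosen after their values were seen, as was the choice to show only the 4 lists with the smallest adjusted p between doses and between solvent groups. Of the lists, 30 had at least 4 tested members and were set against all other tested genes with camera (preset correlation 0.01, Benjamini-Hochberg over lists), and a list that passed is said to have stood apart. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way, were run beside it. A few results for named genes and 1 list are not reported here. In no called list did the median, the mean and the test differ in sign.

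Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values and a minimum of 5 FPKM, rescaling each library to a common sum (TPM), median-of-ratios scaling, a constant prior, the libraries of a time point alone, and leaving out each library in turn. Rescaling to a common sum over nuclear genes and the restriction to protein-coding genes were added after the data were seen. Overlaps and correlations of comparisons that share solvent libraries were set beside 50 simulated draws of unchanged groups. Transcript lengths for the checks of length were those of the longest annotated transcript. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.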

Results

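HCT116 cells, an established human colorectal carcinoma line, were treated with dolastatin 15, a marine peptide that binds tubulin and blocks microtubule assembly, at 20 nM or 100 nM, or with the solvent DMSO, for 16 h or 24 h. Poly(A)-selected RNA of 12 libraries, 2 per group, was sequenced, and the deposited table gives FPKM per gene. The labels call the samples duplicates without saying whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Libraries are numbered as in the table. At 16 h, 1 and 2 are 20 nM, 3 and 4 are 100 nM and 5 and 6 are solvent. At 24 h, 7 and 8 are 20 nM, 9 and 10 are 100 nM and 11 and 12 are solvent. The FPKM sum per library was 911720.3 to 1049886, and 20368 to 21519 genes had a value above 0. Mitochondrially encoded genes held 17.9% to 25.8% of the FPKM sum. At 24 h their share was 17.9% and 18.6% in solvent, 23.8% and 25.8% at 20 nM and 18.8% and 20.7% at 100 nM. MT-ATP8 alone held 7.7%, 8.0%, 11.2%, 12.5%, 7.3% and 8.7% in turn. Read depth is unknown. Pearson correlations across genes (log2 scale) were 0.991 to 0.994 within groups and 0.978 to 0.992 between groups. Positions are GRCh38 coordinates of whole genes, and all means are mean ± SD of 2 libraries.

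The first comparison asked how 20 nM changed expression at 16 h. In the tubulin list, 1 of 12 rose, 8 fell and 3 did not pass (adjusted over the list alone, 1, 8 and 3). TUBB, a beta-tubulin subunit of microtubules (chromosome 6, 30720201 to 30725426), fell from 958 ± 20.0 to 465 ± 5.44 FPKM (SD, n = 2, log2 change -1.04, SE 0.04, adjusted p = 5.57e-06). TUBA1C, an alpha-tubulin (chromosome 12, 49188736 to 49274603, an interval overlapping another alpha-tubulin gene), fell from 1413 ± 17.1 to 715 ± 8.48 FPKM (SD, n = 2, log2 change -0.98, SE 0.04, adjusted p = 5.57e-06). TUBA1B (-0.47) and TUBB4B (-0.32) fell as well, while TUBB6 (0.14) rose (log2 changes). Their median, -0.27, stood apart (camera, adjusted p = 0.000698, and adjusted p = 0.182 with an estimated correlation). Reads of near-identical tubulin copies may be divided uncertainly among these genes. The call at 20 nM and 16 h ended (adjusted p in parentheses) for TUBB6 without library 1, 2, 5 or 6 (0.0670 to 0.129).

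Genes of G2 and mitosis went both ways at 20 nM and 16 h: 20 of 44 rose, 10 fell and 14 did not pass (adjusted over the list alone, 25, 10 and 9). CCNB1, cyclin B1 that drives entry into mitosis (chromosome 5, 69167010 to 69178245), rose from 303 ± 15.1 to 459 ± 12.6 FPKM (SD, n = 2, log2 change 0.60, SE 0.04, adjusted p = 5.01e-05). The mitotic kinases AURKA (0.62) and PLK1 (0.45), the anaphase-promoting complex activator CDC20 (0.60) and the mitotic kinesin KIF20A (0.66) also rose (log2 changes). CDK1, the kinase partner of cyclin B (chromosome 10, 60778331 to 60794852), fell from 71.7 ± 2.12 to 32.2 ± 0.834 FPKM (SD, n = 2, log2 change -1.13, SE 0.05, adjusted p = 1.02e-05), as did TOP2A (-1.01), UBE2C (-0.89), NUSAP1 (-0.91), CKS1B (-0.69) and AURKB (-0.58), which serve chromosome untangling, cyclin destruction, spindle assembly, CDK binding and chromosome attachment. Their median, 0.19, stood apart (camera, adjusted p = 0.000378, and adjusted p = 0.182 with an estimated correlation). Among genes of DNA replication and the G1/S step, 0 of 37 rose, 22 fell and 15 did not pass (adjusted over the list alone, 0, 23 and 14), including the sliding clamp PCNA (-0.42) and the origin licensing factor CDC6 (-0.51). The replication median, -0.23, stood apart (camera, adjusted p = 2.14e-10, and adjusted p = 0.0277 with an estimated correlation).

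Among replication-dependent histone genes at 20 nM and 16 h, 10 of 22 rose, 1 fell and 11 did not pass (adjusted over the list alone, 10, 1 and 11). HIST1H2BC, an H2B gene (chromosome 6, 26114873 to 26123926), rose from 1.36 ± 0.361 to 12.2 ± 1.15 FPKM (SD, n = 2, log2 change 2.49, SE 0.14, adjusted p = 1.95e-05), and HIST1H2AC (1.97) and HIST2H2BE (1.74) rose with it, while HIST2H2AC (-1.30) fell (log2 changes). HIST1H2BJ was at 0 and 0.0900 FPKM in solvent and at 3.26 and 2.34 with 20 nM (adjusted p = 7.43e-05). Outside the list, the histone gene HIST2H2AA4 (1.93) rose. HIST2H2BD, annotated as a pseudogene, was listed at 0 in both solvent libraries and at 3.48 and 3.69 FPKM with 20 nM (adjusted p = 0.00526). The list median, 0.62, stood apart (camera, adjusted p = 4.27e-05, and adjusted p = 0.0602 with an estimated correlation). Many histone genes are near-identical copies, so the share of each is uncertain. Calls at 20 nM and 16 h that ended (adjusted p in parentheses) were HIST2H2AC without library 1, 2, 5 or 6 (0.0804 to 0.118).

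Among cholesterol synthesis genes at 20 nM and 16 h, 0 of 23 rose, 13 fell and 10 did not pass (adjusted over the list alone, 0, 15 and 8). STARD4, a cholesterol transfer protein (chromosome 5, 111496033 to 111512590), fell from 17.4 ± 0.212 to 8.57 ± 0.332 FPKM (SD, n = 2, log2 change -0.94, SE 0.07, adjusted p = 6.65e-05), and INSIG1 (-0.52) and FDFT1 (-0.45), a regulator and an enzyme of the pathway, fell too. Their median, -0.22, stood apart (camera, adjusted p = 4.27e-05, and adjusted p = 0.182 with an estimated correlation). YAP and TEAD targets had a median of -0.12 (camera adjusted p = 0.0203, adjusted p = 0.182 with an estimated correlation). Of 17, 0 were higher and 6 lower (adjusted over the list alone, 0 and 7), and the matrix factor CTGF (-1.02) was among those that fell. SRF and actin genes had a median of 0.08 (camera adjusted p = 0.0316, adjusted p = 0.377 with an estimated correlation). Of 24, 7 were higher and 2 lower (adjusted over the list alone, 8 and 3), and TAGLN (0.71), an actin-binding protein, rose. Mitochondrially encoded genes had a median of 0.13 (camera adjusted p = 0.00359, adjusted p = 0.526 with an estimated correlation). Of 13, 3 were higher and 0 lower (adjusted over the list alone, 3 and 0), including MT-ND6 (0.40) and MT-CYB (0.40). Leaving out 1 library ended the call at 20 nM and 16 h (adjusted p in parentheses) for MT-ND6 without library 1, 2 or 6 (0.0512 to 0.0589), SRF and actin cytoskeleton genes as a list without library 1 or 6 (0.0547 and 0.0579).

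Other large changes at 20 nM and 16 h followed. BCYRN1, a short cytoplasmic RNA derived from an Alu repeat (chromosome 2, 47335315 to 47335514), was listed at 0 in both solvent libraries and at 82.7 and 436 FPKM with 20 nM (adjusted p = 7.22e-05). SLC7A5P2 (1.79) and CCNB3 (1.69) rose, and HMGN1P38 was listed at 0 in solvent and at 1.12 and 3.78 FPKM with 20 nM (adjusted p = 0.0253). Large decreases were SCARNA13 (-2.31), LINC00618 (-1.63), RF00024 (-1.503), MAPK15 (-1.42) and SUCNR1 (-1.25), SCARNA13 being a Cajal body RNA. SNORD17, a small nucleolar RNA, and HBA2 were at 22.5 and 8.85 and at 2.42 and 2.09 FPKM in solvent and at 5.82 and 0 and at 0 and 0.950 with 20 nM (adjusted p = 0.0418 and 0.0343). RN7SL333P was at 2.37 and 1.77 FPKM in solvent and listed at 0 with 20 nM (adjusted p = 0.000198). The call at 20 nM and 16 h ended (adjusted p in parentheses) for HBA2 without library 1, 5 or 6 (0.0991 to 0.188), CCNB3 and HMGN1P38 without library 2, 5 or 6 (0.0938 to 0.156), LINC00618 without library 1, 2, 5, 11 or 12 (0.0503 to 0.193). It also ended for SCARNA13 without library 2, 5, 6, 9, 10, 11 or 12 (0.0647 to 0.255), SNORD17 without library 2, 3, 4, 5, 6, 7, 8, 9, 10, 11 or 12 (0.0518 to 0.219).

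At 20 nM and 16 h, 2388 of 13458 genes passed limma with Benjamini-Hochberg adjustment, 912 higher and 1476 lower, 65 of them by at least 1 on the log2 scale. The split became 1241 higher and 1215 lower under median-of-ratios scaling. Without library 1, 2, 5 or 6 the count was 1041, 1043, 1057 and 1246 in turn. The BCL2 relative BCL2L1 (-0.33) fell and the p53-inducible death factor PMAIP1 (0.23) rose, while the list of p53 targets and that of the BCL2 family were not called. Calls at 20 nM and 16 h that ended (adjusted p in parentheses) were BCL2L1 without library 1, 2 or 5 (0.0628 to 0.0899), PMAIP1 without library 2, 5 or 6 (0.0503 to 0.0962).

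At 100 nM and 16 h the same question was asked of the higher dose. In the tubulin list, 2 of 12 rose, 7 fell and 3 did not pass (adjusted over the list alone, 2, 8 and 2). TUBB fell from 958 ± 20.0 to 431 ± 4.16 FPKM (SD, n = 2, log2 change -1.15, SE 0.04, adjusted p = 6.87e-07), TUBA1C (-1.004), TUBA1B (-0.49) and TUBB4B (-0.27) fell, and TUBB6 (0.21) and TUBB2A (0.23) rose (log2 changes). Their median, -0.22, stood apart (camera, adjusted p = 0.0103, and adjusted p = 0.242 with an estimated correlation). Of the G2 and mitosis genes, 27 of 44 rose, 10 fell and 7 did not pass (adjusted over the list alone, 30, 10 and 4). CCNB1 rose from 303 ± 15.1 to 520.4 ± 13.5 FPKM (SD, n = 2, log2 change 0.78, SE 0.04, adjusted p = 5.62e-06), and AURKA (0.83), KIF20A (0.79), PLK1 (0.65) and CDC20 (0.65) rose, whereas CDK1 (-1.31), TOP2A (-1.22), UBE2C (-1.03) and NUSAP1 (-1.03) fell. The mitotic median, 0.31, stood apart (camera, adjusted p = 4.59e-06, and adjusted p = 0.144 with an estimated correlation). FBXO5, an inhibitor of the anaphase-promoting complex (chromosome 6, 152970519 to 152983579), fell from 38.1 ± 0.629 to 11.6 ± 0.0919 FPKM (SD, n = 2, log2 change -1.64, SE 0.05, adjusted p = 6.87e-07). A library left out ended the call at 100 nM and 16 h (adjusted p in parentheses) for TUBB2A without library 6 (0.0614).

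Among replication genes at 100 nM and 16 h, 0 of 37 rose, 26 fell and 11 did not pass (adjusted over the list alone, 0, 30 and 7). CCNE2, cyclin E2 of the G1/S step (chromosome 8, 94879770 to 94896678), fell from 30.7 ± 1.88 to 11.7 ± 0.431 FPKM (SD, n = 2, log2 change -1.32, SE 0.10, adjusted p = 3.98e-05), with CDC6 (-0.88), MCM5 (-0.57), PCNA (-0.55) and ORC1 (-0.35). Their median, -0.35, stood apart (camera, adjusted p = 4.05e-13, and adjusted p = 0.0149 with an estimated correlation). Histone genes had a median of 0.01 that did not stand apart (camera adjusted p = 0.0780). Of 22, 8 were higher and 2 lower (adjusted over the list alone, 8 and 3), and HIST1H2BC (1.71) rose, with HIST1H2BJ at 0 and 0.0900 FPKM in solvent and at 2.26 and 2.18 with 100 nM, and HIST2H2BD, outside the list, listed at 0 in solvent and at 4.40 and 1.67 FPKM with 100 nM (adjusted p = 8.89e-05 and 0.00704). SRF and actin genes had a median of 0.14 (camera adjusted p = 3.64e-05, adjusted p = 0.144 with an estimated correlation). Of 24, 11 were higher and 1 lower (adjusted over the list alone, 14 and 2), including TAGLN (1.201). ERK output genes had a median of -0.23 (camera adjusted p = 0.0434, adjusted p = 0.373 with an estimated correlation). Of 18, 2 were higher and 9 lower (adjusted over the list alone, 3 and 10), and DUSP6 (-1.13), a phosphatase of ERK, fell. The call at 100 nM and 16 h ended (adjusted p in parentheses) for ERK output genes as a list without library 3, 5, 7, 8, 9 or 10 (0.0508 to 0.0627).

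Other lists called at 100 nM and 16 h followed. YAP and TEAD targets had a median of -0.18 (camera adjusted p = 0.0434, adjusted p = 0.263 with an estimated correlation). Of 17, 2 were higher and 6 lower (adjusted over the list alone, 3 and 9), and CTGF (-1.51) fell. Wnt targets had a median of -0.29 (camera adjusted p = 0.0434, adjusted p = 0.242 with an estimated correlation). Of 14, 1 were higher and 6 lower (adjusted over the list alone, 2 and 7), including SOX4 (-1.01). Heat shock genes had a median of 0.09 (camera adjusted p = 0.0331, adjusted p = 0.373 with an estimated correlation). Of 14, 6 were higher and 2 lower (adjusted over the list alone, 7 and 2), among them the constitutive chaperone HSPA8 (0.33) higher and HSPA1B (-0.41) lower, the latter near-identical to HSPA1A. Cytosolic ribosomal protein genes had a median of 0.06 (camera adjusted p = 0.0179, adjusted p = 0.651 with an estimated correlation). Of 32, 2 were higher and 0 lower (adjusted over the list alone, 1 and 0). Mitochondrially encoded genes had a median of 0.21 (camera adjusted p = 0.000120, adjusted p = 0.381 with an estimated correlation). Of 13, 5 were higher and 0 lower (adjusted over the list alone, 7 and 0), including MT-ND6 (0.55) and MT-CYB (0.49). Calls at 100 nM and 16 h that ended (adjusted p in parentheses) were YAP and TEAD target genes as a list without library 3, 4, 5, 6, 7, 8, 9, 10, 11 or 12 (0.05004 to 0.0627), Wnt target genes as a list without library 3, 4, 6, 7, 8, 9 or 10 (0.0505 to 0.0669), heat shock genes as a list without library 5 (0.0521). Further calls that ended were cytosolic ribosomal protein genes as a list without library 3 or 6 (0.174 and 0.0743).

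Other large increases at 100 nM and 16 h were SLC7A5P2 (1.98), MRPS30-DT (1.71), SMG1P4 (1.63), GUSBP3 (1.53) and SMG1P3 (1.43), mostly pseudogenes, and the matrix protein TNC (1.31). BCYRN1 was listed at 0 in solvent and at 229 and 232 FPKM with 100 nM (adjusted p = 3.09e-05). Among decreases, SCARNA13 (-2.33), MAPK15 (-1.74), SUCNR1 (-1.53), RBM23 (-1.51) and TREX1 (-1.40) fell (log2 changes), TREX1 being a DNA exonuclease and SUCNR1 the succinate receptor. RAB4B-EGLN2, a readthrough gene, was at 3.03 and 3.08 FPKM in solvent and at 1.18 and 0 with 100 nM (adjusted p = 0.0188). SNORD17 was at 22.5 and 8.85 FPKM in solvent and listed at 0 with 100 nM (adjusted p = 0.00512), as was RN7SL333P (2.37 and 1.77 FPKM in solvent, adjusted p = 0.000120). Leaving out 1 library ended the call at 100 nM and 16 h (adjusted p in parentheses) for SMG1P4 without library 4 or 5 (0.0870 to 0.0893), MRPS30-DT without library 3, 5 or 6 (0.0666 to 0.0844), RAB4B-EGLN2 without library 4, 5 or 6 (0.0775 to 0.0945). Likewise ended GUSBP3 without library 3, 4, 5 or 6 (0.0604 to 0.0748), SCARNA13 without library 3, 5, 6, 9, 10, 11 or 12 (0.0509 to 0.202).

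With 100 nM at 16 h, 3205 of 13458 genes were called, 1233 higher and 1972 lower, 123 of them by at least 1 on the log2 scale. The split became 911 higher and 2378 lower under rescaling to a common sum and 1642 higher and 1653 lower under median-of-ratios scaling. Without library 3, 4, 5 or 6 the count was 2008, 1906, 1782 and 1851 in turn.

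At 24 h the 20 nM groups were compared with the solvent of that time. Of the G2 and mitosis genes, 0 of 44 rose, 33 fell and 11 did not pass (adjusted over the list alone, 0, 37 and 7). CDK1 fell from 61.9 ± 0.530 to 49.4 ± 0.226 FPKM (SD, n = 2, log2 change -0.32, SE 0.05, adjusted p = 0.00310), and PLK1 (-0.45), AURKA (-0.23), CCNB1 (-0.18), UBE2C (-0.58) and AURKB (-0.61) fell (log2 changes). Their median, -0.27, stood apart (camera, adjusted p = 4.03e-14, and adjusted p = 0.0242 with an estimated correlation). In the tubulin list, 0 of 12 rose, 7 fell and 5 did not pass (adjusted over the list alone, 0, 7 and 5), with TUBB lower from 1056 ± 19.2 to 771 ± 24.5 FPKM (SD, n = 2, log2 change -0.45, SE 0.04, adjusted p = 0.000140) and TUBA1C (-0.70) and TUBB4B (-0.54) lower. The tubulin median, -0.26, stood apart (camera, adjusted p = 5.57e-05, and adjusted p = 0.0496 with an estimated correlation). Microtubule-associated proteins had a median of -0.24 (camera adjusted p = 7.79e-05, adjusted p = 0.0478 with an estimated correlation). Of 21, 1 were higher and 11 lower (adjusted over the list alone, 1 and 14), such as the polymerase CKAP5 (-0.47) and the destabiliser STMN1 (-0.30). The call at 20 nM and 24 h ended (adjusted p in parentheses) for CCNB1 without library 11 or 12 (0.05001 to 0.0570).

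In the replication list at 20 nM and 24 h, 16 of 37 rose, 1 fell and 20 did not pass (adjusted over the list alone, 18, 1 and 18), and CDC6 (0.45), RFC4 (0.46), ORC1 (0.44) and PCNA (0.24) rose, although under rescaling to a common sum the list's median turned to -0.06, or 0.10 relative to all genes. Their median, 0.13, stood apart (camera, adjusted p = 7.79e-05, and adjusted p = 0.0496 with an estimated correlation). Of the histone genes, 15 of 22 rose, 0 fell and 7 did not pass (adjusted over the list alone, 15, 0 and 7). HIST2H2AA4, an H2A gene outside the list (chromosome 1, 149851061 to 149851624), rose from 10.1 ± 1.04 to 114 ± 4.29 FPKM (SD, n = 2, log2 change 3.37, SE 0.10, adjusted p = 1.29e-06). HIST1H2BC (3.08), HIST1H2BK (2.84), HIST1H2AC (2.82), HIST2H2BE (2.63), HIST1H1C (2.55), HIST1H4H (2.45) and HIST1H2BJ (2.38) were among the largest increases. The histone median, 1.60, stood apart (camera, adjusted p = 1.16e-10, and adjusted p = 0.0157 with an estimated correlation). Of the immediate early genes, which encode fast-responding transcription factors, 15 of 24 rose, 4 fell and 5 did not pass (adjusted over the list alone, 16, 4 and 4), with EGR1 (1.12), JUN (0.97), FOSB (1.40) and FOSL1 (0.61). The early-gene median, 0.33, stood apart (camera, adjusted p = 2.83e-05, and adjusted p = 0.188 with an estimated correlation).

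Of the cholesterol synthesis genes at 20 nM and 24 h, 0 of 23 rose, 18 fell and 5 did not pass (adjusted over the list alone, 1, 18 and 4). STARD4 fell from 18.1 ± 0.940 to 9.44 ± 0.559 FPKM (SD, n = 2, log2 change -0.87, SE 0.07, adjusted p = 9.66e-05), and INSIG1 (-0.80) and FDFT1 (-0.67) fell. Their median, -0.34, stood apart (camera, adjusted p = 4.32e-09, and adjusted p = 0.0496 with an estimated correlation). Interferon response genes had a median of 0.24 (camera adjusted p = 0.00290, adjusted p = 0.0496 with an estimated correlation). Of 19, 9 were higher and 2 lower (adjusted over the list alone, 10 and 2), and IFIT2 (1.79), IFIT1 (1.07) and OASL (0.97) rose. Heat shock genes had a median of -0.13 (camera adjusted p = 0.00134, adjusted p = 0.159 with an estimated correlation). Of 14, 1 were higher and 7 lower (adjusted over the list alone, 1 and 7), including HSPA1A (-1.12), HSPA1B (-0.89), DNAJB1 (-0.54) and HSPA8 (-0.47). Mitochondrially encoded genes had a median of 0.57 (camera adjusted p = 4.32e-09, adjusted p = 0.159 with an estimated correlation). Of 13, 12 were higher and 0 lower (adjusted over the list alone, 13 and 0), including MT-ATP8 (0.79), MT-ND6 (0.95) and MT-CYB (0.75).

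ERK output genes had a median of 0.14 (camera adjusted p = 0.0317, adjusted p = 0.254 with an estimated correlation). Of 18, 7 were higher and 2 lower (adjusted over the list alone, 8 and 2), with a median of -0.05 under rescaling to a common sum (0.12 relative to all genes). Autophagy genes had a median of 0.18 (camera adjusted p = 0.0456, adjusted p = 0.245 with an estimated correlation). Of 17, 8 were higher and 0 lower (adjusted over the list alone, 8 and 2). Cytosolic ribosomal protein genes had a median of 0.07 (camera adjusted p = 0.0218, adjusted p = 0.587 with an estimated correlation). Of 32, 12 were higher and 1 lower (adjusted over the list alone, 12 and 2), with a median of -0.12 under rescaling to a common sum and -0.00260 over nuclear genes (0.04 and 0.05 relative to all genes). Calls at 20 nM and 24 h that ended (adjusted p in parentheses) were ERK output genes as a list without library 8 (0.0689), autophagy genes as a list without library 1, 2, 5, 6, 7, 9, 10 or 12 (0.0501 to 0.0586), cytosolic ribosomal protein genes as a list without library 7 (0.704).

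The 7SK RNA, RN7SK (2.55), also rose at 20 nM and 24 h, and SNRPGP15, a pseudogene, was at 8.72 and 0 FPKM in solvent and at 50.8 and 43.0 with 20 nM (adjusted p = 0.00893). Large decreases were CCNB3 (-1.95), TMEM265 (-1.39), NEURL1B (-1.17), OLFM2 (-1.16), SDC1 (-1.15) and PLEKHA8P1 (-1.13) (log2 changes), of which OLFM2 is a secreted olfactomedin (chromosome 19, 9853718 to 9936552) and SDC1 a cell-surface proteoglycan. BCYRN1, RF02164 and HMGN1P38 were at 609.7 and 719, 94.2 and 109 and 4.18 and 1.24 FPKM in the 2 solvent libraries and were each listed at 0 with 20 nM (adjusted p = 2.84e-05, 0.00980 and 0.0129). A library left out ended the call at 20 nM and 24 h (adjusted p in parentheses) for CCNB3 and HMGN1P38 without library 11 (0.0591 to 0.0825), RN7SK without library 12 (0.0892), PLEKHA8P1 without library 7 or 12 (0.0534 to 0.0841).

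At 20 nM and 24 h, 3880 of 13458 genes were called, 1984 higher and 1896 lower, 84 of them by at least 1 on the log2 scale. The split became 573 higher and 4662 lower under rescaling to a common sum and 1332 higher and 2684 lower under rescaling over nuclear genes. Without library 11 or 12 the count was 2153 and 2440 in turn. The median log2 change of all genes shifted by -0.16 under rescaling to a common sum.

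At 100 nM and 24 h the higher dose was set against the same solvent. Of the G2 and mitosis genes, 4 of 44 rose, 29 fell and 11 did not pass (adjusted over the list alone, 4, 29 and 11). TOP2A fell from 53.5 ± 2.22 to 27.1 ± 1.39 FPKM (SD, n = 2, log2 change -0.96, SE 0.06, adjusted p = 1.43e-05), and UBE2C (-1.01), CKS1B (-0.998), AURKB (-0.96), CDK1 (-0.86) and NUSAP1 (-0.85) fell, while CDC20 (0.35) and CCNB1 (0.16) rose (log2 changes). Their median, -0.32, stood apart (camera, adjusted p = 1.96e-07, and adjusted p = 0.0835 with an estimated correlation). In the tubulin list, 2 of 12 rose, 7 fell and 3 did not pass (adjusted over the list alone, 2, 7 and 3). TUBA1C fell from 1474 ± 0.191 to 676 ± 25.2 FPKM (SD, n = 2, log2 change -1.12, SE 0.04, adjusted p = 7.23e-07), TUBB fell from 1056 ± 19.2 to 576 ± 20.3 FPKM (SD, n = 2, log2 change -0.87, SE 0.04, adjusted p = 2.31e-06), and TUBB6 (0.20) and TUBB2A (0.15) rose. The tubulin median, -0.30, stood apart (camera, adjusted p = 0.00342, and adjusted p = 0.198 with an estimated correlation). Microtubule-associated proteins had a median of -0.23 (camera adjusted p = 0.000629, adjusted p = 0.0835 with an estimated correlation). Of 21, 1 were higher and 9 lower (adjusted over the list alone, 1 and 14), including CKAP5 (-0.83) and MAP1B (-0.60). The call at 100 nM and 24 h ended (adjusted p in parentheses) for CCNB1 without library 9, 10, 11 or 12 (0.0585 to 0.0880), TUBB2A without library 1, 2, 3, 4, 9, 10, 11 or 12 (0.0512 to 0.176).

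Of the histone genes at 100 nM and 24 h, 12 of 22 rose, 0 fell and 10 did not pass (adjusted over the list alone, 14, 0 and 8). HIST1H2BK, an H2B gene (chromosome 6, 27146418 to 27146798), rose from 23.1 ± 7.64 to 220.3 ± 6.37 FPKM (SD, n = 2, log2 change 3.24, SE 0.19, adjusted p = 9.53e-06), and HIST1H2BC (3.40), HIST1H2AC (2.99996), HIST2H2BE (2.77), HIST1H1C (2.37), HIST1H2BD (2.31) and HIST1H2BJ (2.26) rose, as did HIST2H2AA4 (3.43) outside the list. The list median, 1.003, stood apart (camera, adjusted p = 2.78e-08, and adjusted p = 0.0284 with an estimated correlation). Replication genes had a median of 0.02 that did not stand apart (camera adjusted p = 0.142). Of 37, 11 were higher and 7 lower (adjusted over the list alone, 14 and 8), including CCNE2 (0.63) and ORC1 (0.33). Among immediate early genes, 17 of 24 rose, 5 fell and 2 did not pass (adjusted over the list alone, 17, 5 and 2). EGR1, a zinc-finger factor (chromosome 5, 138465490 to 138469315), rose from 21.4 ± 0.969 to 50.5 ± 1.17 FPKM (SD, n = 2, log2 change 1.1995, SE 0.08, adjusted p = 1.98e-05), with FOSB (1.70), JUN (1.36), FOSL1 (1.002) and FOS (0.71). The early-gene median, 0.46, stood apart (camera, adjusted p = 1.49e-05, and adjusted p = 0.284 with an estimated correlation). Interferon response genes had a median of 0.19 that did not stand apart (camera adjusted p = 0.138). Of 19, 7 were higher and 4 lower (adjusted over the list alone, 7 and 4), including IFIT2 (1.84), OASL (1.13) and IFIT1 (0.93). Calls at 100 nM and 24 h that ended (adjusted p in parentheses) were FOS without library 9, 10 or 12 (0.0640 to 0.190).

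Other lists were called at 100 nM and 24 h. Cholesterol synthesis genes had a median of -0.30 (camera adjusted p = 3.32e-06, adjusted p = 0.185 with an estimated correlation). Of 23, 1 were higher and 17 lower (adjusted over the list alone, 2 and 17), including STARD4 (-1.19), INSIG1 (-0.94) and FDFT1 (-0.81). Heat shock genes had a median of -0.15 (camera adjusted p = 0.00912, adjusted p = 0.342 with an estimated correlation). Of 14, 2 were higher and 8 lower (adjusted over the list alone, 3 and 8), including HSPA1B (-1.19), HSPA1A (-1.07) and DNAJB1 (-0.92). Cytosolic ribosomal protein genes had a median of 0.14 (camera adjusted p = 1.49e-05, adjusted p = 0.388 with an estimated correlation). Of 32, 12 were higher and 0 lower (adjusted over the list alone, 16 and 0). Oxidative phosphorylation genes had a median of 0.12 (camera adjusted p = 0.0454, adjusted p = 0.552 with an estimated correlation). Of 30, 10 were higher and 3 lower (adjusted over the list alone, 11 and 4). Mitochondrially encoded genes had a median of 0.30 (camera adjusted p = 5.95e-05, adjusted p = 0.371 with an estimated correlation). Of 13, 9 were higher and 0 lower (adjusted over the list alone, 10 and 0), including MT-ND6 (0.63) and MT-CYB (0.58). Leaving out 1 library ended the call at 100 nM and 24 h (adjusted p in parentheses) for oxidative phosphorylation genes as a list without library 5, 6, 9, 10, 11 or 12 (0.0579 to 0.0815).

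RPS26P6, a ribosomal protein pseudogene, was listed at 0 in both solvent libraries at 24 h and at 21.6 and 38.5 FPKM with 100 nM (adjusted p = 2.38e-06), and SNRPGP15 was at 8.72 and 0 and at 23.4 and 24.3 FPKM (adjusted p = 0.0247). Among decreases, OLFM2 (-1.501), GMPR (-1.47), NEURL1B (-1.46), RF00024 (-1.44), FLOT2 (-1.43), FAM83D (-1.41), H19 (-1.40), SDC3 (-1.28) and TRIOBP (-1.28) fell (log2 changes). FLOT2 is a membrane scaffold protein (chromosome 17, 28879335 to 28897679), FAM83D a spindle protein, GMPR a guanine nucleotide reductase and H19 an imprinted noncoding RNA. RF02164 was at 94.2 and 109 FPKM in solvent and listed at 0 with 100 nM (adjusted p = 0.00809). Of the HIF and hypoxia list, VEGFA (-0.73) and P4HA2 (-1.25) fell, with 7 higher and 6 lower of 32 (camera adjusted p = 0.375). The call at 100 nM and 24 h ended (adjusted p in parentheses) for SNRPGP15 without library 9, 10 or 12 (0.0645 to 0.0905).

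With 100 nM at 24 h, 4550 of 13458 genes were called, 2075 higher and 2475 lower, 115 of them by at least 1 on the log2 scale. The split became 1146 higher and 3725 lower under rescaling to a common sum, 2471 higher and 2174 lower under median-of-ratios scaling and 1439 higher and 3335 lower under rescaling over nuclear genes. Without library 9, 11 or 12 the count was 2757, 2996 and 2957 in turn.

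**Figure D1:**
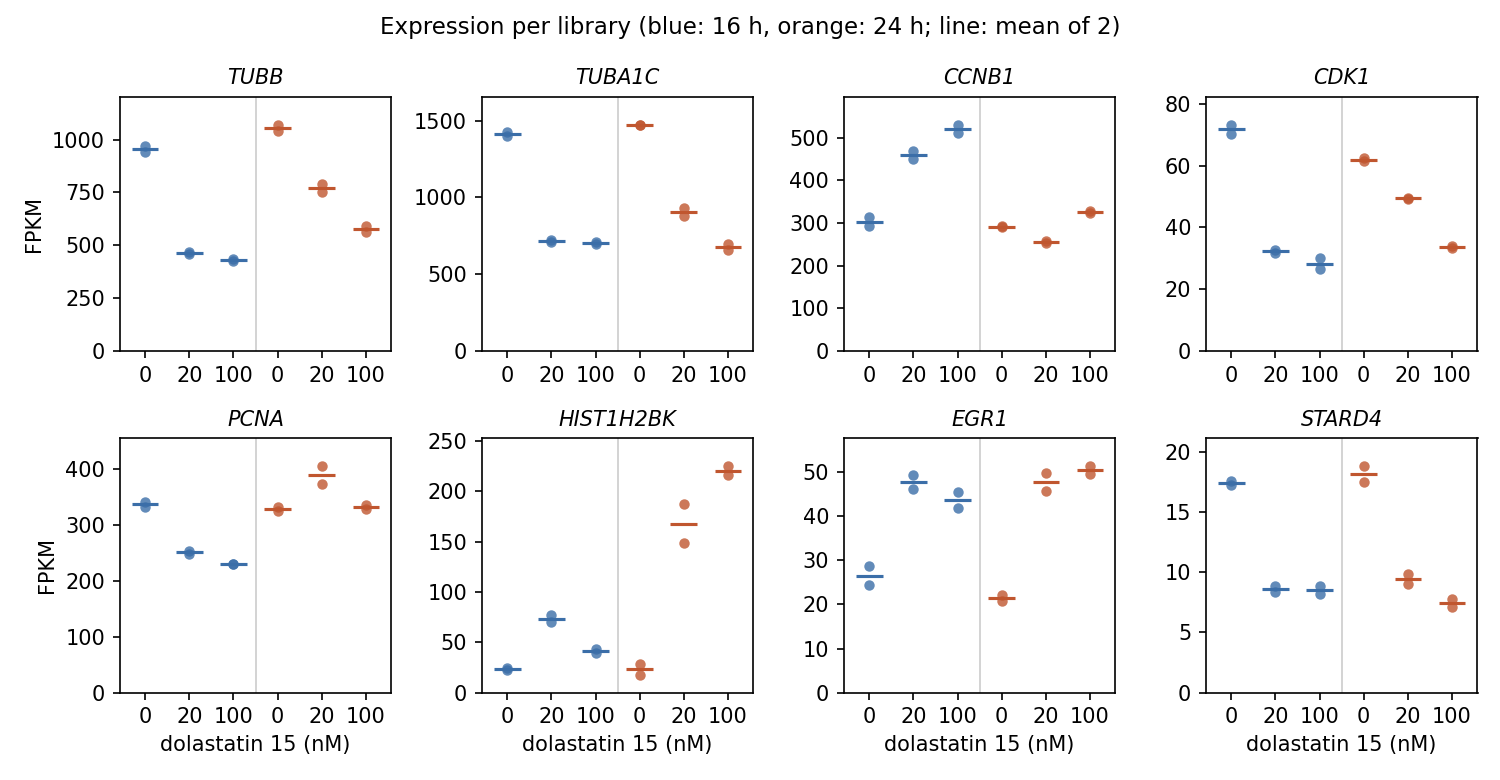
FPKM (vertical axes) of TUBB, TUBA1C, CCNB1, CDK1, PCNA, HIST1H2BK, EGR1 and STARD4 in each of the 12 libraries by dose (horizontal axes), at 16 h and 24 h, each point being 1 library. Both drug libraries of TUBB lie below both solvent libraries at each dose and time, and the histone HIST1H2BK lies highest at 24 h with drug, under the scaling as deposited.

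**Figure D2:**
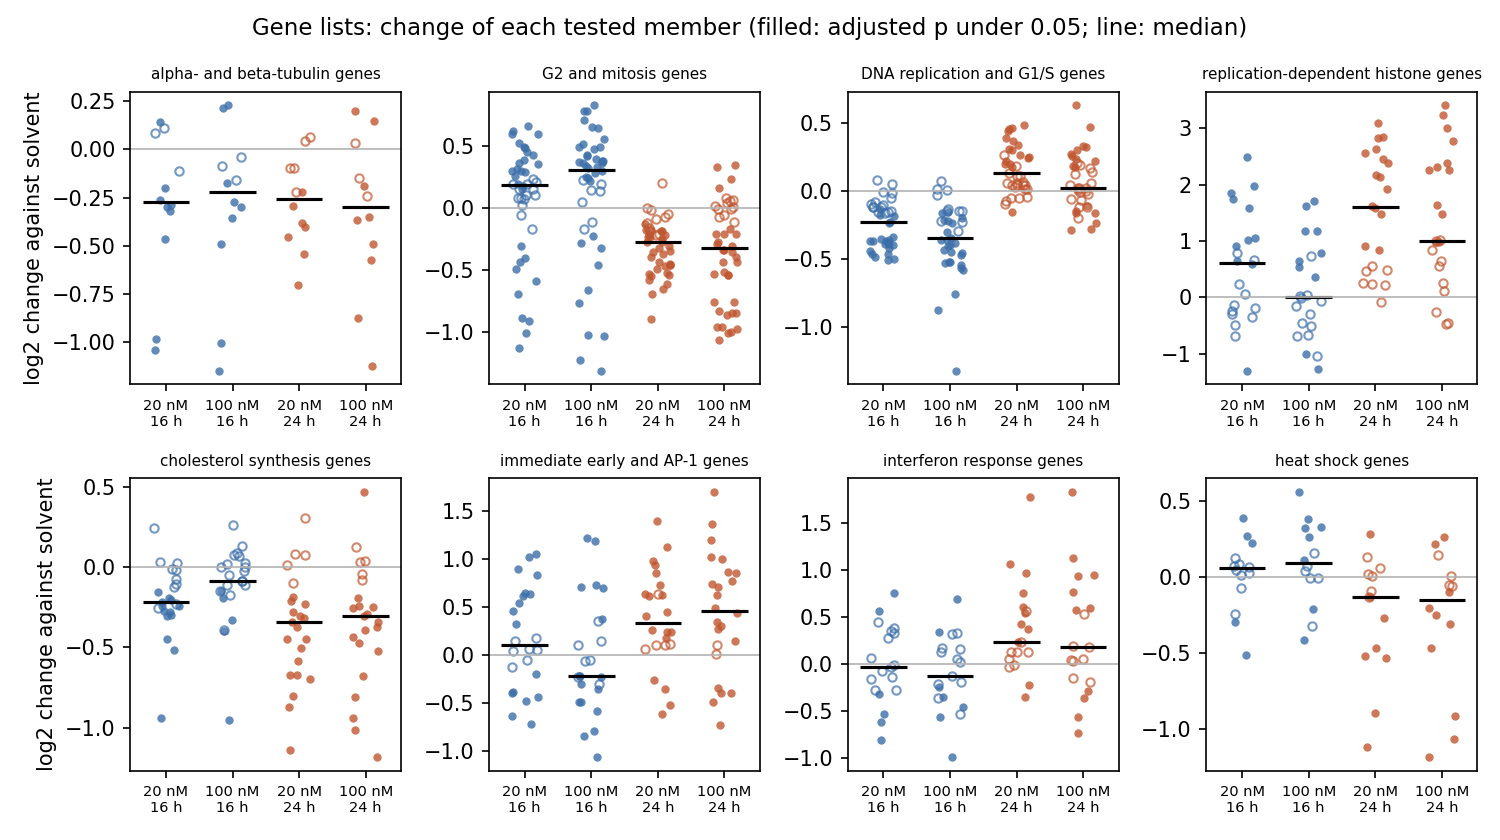
Log2 changes on the log2(FPKM + 1) scale (vertical axes) of the members of 8 gene lists in the 4 drug comparisons, with called members filled and the line at the list's median. The G2 and mitosis median is 0.31 at 100 nM and 16 h and -0.32 at 24 h, and the replication median at 20 nM and 24 h of 0.13 turns to -0.06 under rescaling to a common sum.

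Camera called these further fixed lists in none of the 4 drug comparisons, and its lowest adjusted p over the 4 stands last. At 100 nM and 24 h, 3 and 6 of 15 gamma-tubulin complex and cofactor genes, 10 and 5 of 35 p53 target genes, 5 and 1 of 13 BCL2 family genes and 7 and 6 of 32 HIF and hypoxia target genes rose and fell (adjusted over the list alone, 4 and 6, 10 and 5, 5 and 1, 7 and 6), with lowest adjusted p 0.535, 0.242, 0.192 and 0.375. Likewise, 4 and 5 of 19 glycolysis enzymes, 2 and 3 of 15 angiogenic factors, 3 and 7 of 21 unfolded protein response genes and 9 and 3 of 21 ATF4 response genes rose and fell (adjusted over the list alone, 4 and 5, 2 and 4, 3 and 7, 10 and 4), with lowest adjusted p 0.128, 0.305, 0.0723 and 0.110. In the next lists, 4 and 2 of 11 NF-kB target genes, 5 and 7 of 18 NRF2 target genes, 2 and 5 of 12 epithelial genes and 2 and 2 of 6 fibroblast and mesenchymal markers rose and fell (adjusted over the list alone, 4 and 2, 5 and 7, 2 and 6, 2 and 2), with lowest adjusted p 0.374, 0.0604, 0.162 and 0.267.

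CDKN1A and MDM2, the p21 and MDM2 genes of the p53 pathway, had log2 changes of 0.08 and -0.14 at 100 nM and 24 h and were called in none of the 4 comparisons. Markers of differentiated colon epithelium (2 tested of 18), blood cells (3 of 12) and endothelium (1 of 8) had too few members above the filter for a list test, and at 100 nM and 24 h 1, 0 and 0 of them fell and 0, 1 and 0 rose by limma.

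Across the 4 drug comparisons, 772 genes were called in the same direction in each, 278 higher and 494 lower, and 53 were called in each with mixed directions. Of the 5 increases with the largest smallest change, HIST1H2BJ had a library at 0 and the others were the histone genes HIST1H2BC (1.71 to 3.40), HIST2H2AA4 (1.23 to 3.43), HIST2H2BE (1.18 to 2.77) and HIST1H2AC (1.18 to 2.99996), with the lowest and highest log2 change in parentheses. The 5 decreases were FLOT2 (-1.43 to -0.88), STARD4 (-1.19 to -0.87), OLFM2 (-1.501 to -0.86), CRTAP (-1.22 to -0.85) and BEX3 (-1.26 to -0.83). CRTAP takes part in collagen hydroxylation. The doses shared 1911 calls at 16 h (696 higher and 1215 lower, where independent lists would share 83.6 and 216) and 2768 at 24 h (1340 and 1428, against 306 and 349). Unchanged groups simulated with a shared solvent pair shared 0 calls in limma. At an unadjusted p under 0.05 the mean was 174 at 16 h and 178 at 24 h (50 draws), against 3250 and 3908 observed. Both doses shared 2 solvent libraries, too few to leave 2 for each dose, so part of the excess may come from them. The draws may understate that part. Calls shared by all 4 numbered 442, 443, 429, 446 and 512 without library 1, 2, 5, 6 or 11 in turn. Calls shared at 16 h numbered 933, 940, 916 and 1001 without library 1, 2, 5 or 6 in turn. Calls shared at 24 h numbered 1567 and 1716 without library 11 or 12 in turn.

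The correlation of log2 changes across genes, which are not independent replicates, was 0.76 between doses at 16 h (simulated 0.50) and 0.73 at 24 h (simulated 0.51). The covariance was 0.0691 against a simulated 0.0166 at 16 h and 0.0820 against 0.0167 at 24 h. The times share no library but share each gene's fitted variance and were not simulated, so independent lists are no valid baseline. At 20 nM, 1002 calls were shared (393 higher and 609 lower, against 134 and 208) and 183 were opposite. The correlation was 0.18 (0.37 over protein-coding genes, rank correlation 0.32). For 100 nM, 1661 calls were shared (626 and 1035, against 190.1 and 363), 168 were opposite, and the correlation was 0.38 (0.48 over protein-coding genes, rank correlation 0.44). Calls shared by the times at 20 nM numbered 491, 501, 509, 559, 640 and 666 without library 1, 2, 5, 6, 11 or 12 in turn. Calls shared by the times at 100 nM numbered 1069, 1090, 1003 and 1037 without library 3, 4, 5 or 6 in turn.

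**Figure D3:**
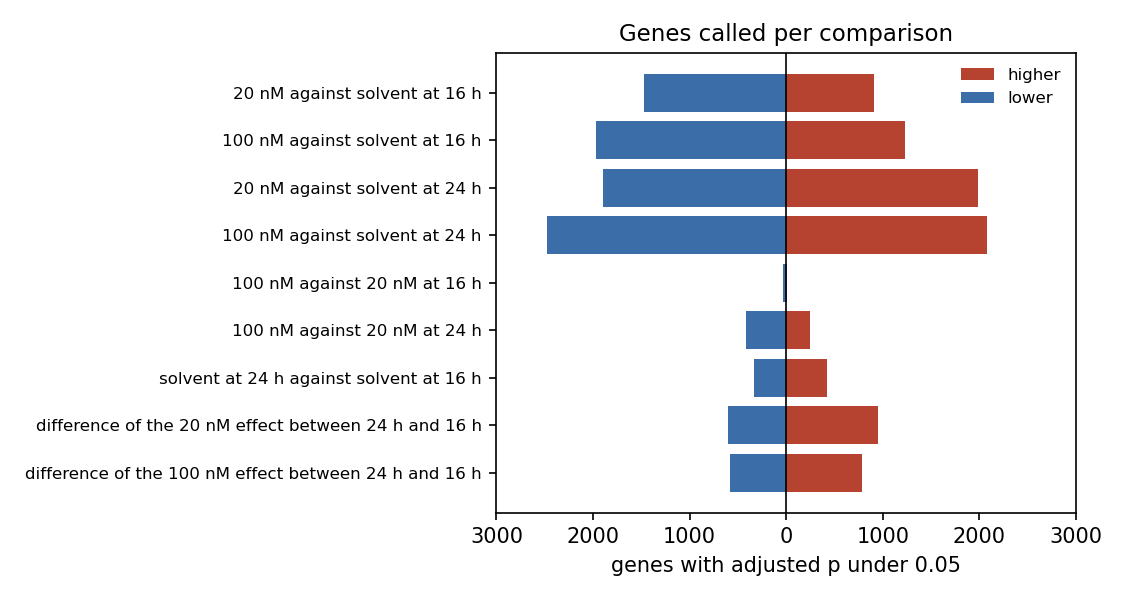
Number of genes called (horizontal axis) higher and lower by limma at adjusted p under 0.05 in each of the 9 comparisons (vertical axis). The 4 drug comparisons hold 2388 to 4550 calls and the dose comparison at 16 h holds 43.

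The direct comparison of 100 nM with 20 nM at 16 h called few genes. CD44 (0.35), ANXA3 (0.26), TSPAN5 (0.29), ASB8 (0.38) and HSPA8 (0.26) were higher at 100 nM (log2 changes), of which CD44 is the hyaluronan receptor and ANXA3 an annexin. CCNE2 was lower, from 22.0 ± 2.17 to 11.7 ± 0.431 FPKM (SD, n = 2, log2 change -0.86, SE 0.10, adjusted p = 0.0137), as were LINC00476 (-0.83), NR4A2 (-0.77), HIST2H2AA4 (-0.70) and HES1 (-0.68), the last a Notch-regulated repressor, and DUSP6 (-0.62) and SOX4 (-0.42). Between these groups, 43 of 13458 genes were called, 6 higher and 37 lower, 3 of them by at least 1 on the log2 scale. The split became 2 higher and 57 lower under rescaling to a common sum. Without library 1, 2, 3, 4, 5, 6, 7 or 8 the count was 16, 15, 18, 16, 23, 23, 65 and 65 in turn. With the libraries of that time alone 18 were called, each of them lower, and with a constant prior 28. Calls between doses at 16 h that ended (adjusted p in parentheses) were LINC00476 without library 1, 2 or 4 (0.0697 to 0.140), CCNE2 and SOX4 without library 2, 3 or 4 (0.0546 to 0.133), DUSP6 without library 1, 2, 3 or 4 (0.0925 to 0.144). Others that ended were HIST2H2AA4 without library 1, 3, 4, 5, 6, 9 or 10 (0.0546 to 0.180), ANXA3 without library 1, 2, 3, 4, 5, 6, 9 or 10 (0.0939 to 0.248), CD44 without library 1, 2, 3, 4, 5, 6, 11 or 12 (0.0622 to 0.186). It also ended for NR4A2 without library 1, 2, 3, 5, 6, 9, 10, 11 or 12 (0.0798 to 0.207), ASB8, HSPA8 and TSPAN5 without library 1, 2, 3, 4, 5, 6, 9, 10, 11 or 12 (0.0506 to 0.240).

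Of 10 lists called between doses at 16 h, the 4 with the smallest adjusted p had these median log2 differences. At 100 nM against 20 nM they were histone genes -0.51, immediate early genes -0.23, SRF and actin genes 0.08 and cholesterol synthesis genes 0.11 (camera adjusted p = 8.58e-08, 6.72e-08, 2.76e-07 and 4.12e-07), with adjusted p = 0.0369, 0.0921, 0.0663 and 0.0827 with an estimated correlation. Higher and lower members were 0 and 0 of 22, 0 and 2 of 24, 0 and 0 of 24, and 0 and 0 of 23 (adjusted over the list alone, 1 and 11, 1 and 10, 7 and 0, 2 and 0). At an unadjusted p under 0.05 in limma they were 1 and 13, 1 and 14, 8 and 0, 8 and 0. Over all lists, 7 of 8 member calls between doses at 16 h ended without at least 1 library.

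The doses were also compared at 24 h. STC2, a secreted glycoprotein (chromosome 5, 173314713 to 173329503), was higher at 100 nM, from 22.1 ± 1.26 to 37.4 ± 3.92 FPKM (SD, n = 2, log2 change 0.73, SE 0.11, adjusted p = 0.0115), and so were SMARCA5-AS1 (2.27) and POLR2L (0.71) (log2 changes). BCYRN1 and RPS26P6 were listed at 0 in both 20 nM libraries and at 395 and 430.2 and at 21.6 and 38.5 FPKM at 100 nM (adjusted p = 0.000428 and 4.34e-05). C19orf81 (-0.81), UCP2 (-0.76), DHRS3 (-0.71), SUCNR1 (-0.71) and RPS3AP26 (-0.67) were lower, UCP2 being a mitochondrial carrier and DHRS3 a retinal reductase. TOP2A (-0.60), CDK1 (-0.54) and TUBB (-0.42) were lower as well. Between the doses at 24 h, 657 of 13458 genes were called, 245 higher and 412 lower, 10 of them by at least 1 on the log2 scale. The split became 797 higher and 166 lower under rescaling to a common sum and 392 higher and 284 lower under median-of-ratios scaling. Without library 1, 2, 5, 6, 7, 8, 9, 10 or 12 the count was 341, 341, 412, 413, 1526, 121, 41, 78 and 437 in turn. The count was 10 with the libraries of that time alone, 411 with a constant prior and 334 with no filter on low values. A library left out ended the call between doses at 24 h (adjusted p in parentheses) for DHRS3 without library 9 (0.0766), STC2 without library 8 or 9 (0.0725 to 0.0941), RPS3AP26 without library 9 or 10 (0.109 to 0.150). Further calls that ended were C19orf81, POLR2L and UCP2 without library 8, 9 or 10 (0.0771 to 0.138), SMARCA5-AS1 without library 1, 2, 5, 6, 7, 8, 9 or 10 (0.0594 to 0.170).

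Between doses at 24 h, 8 lists were called, without the tubulin list (2 higher and 3 lower of 12, adjusted over the list alone 2 and 3, camera adjusted p = 0.756). The 4 with the smallest adjusted p had medians of SRF and actin genes 0.13, mitochondrially encoded genes -0.27, replication genes -0.11 and BCL2 family genes 0.15 (camera adjusted p = 2.39e-07, 0.000160, 0.00154 and 0.00833), with adjusted p = 0.162, 0.549, 0.235 and 0.549 with an estimated correlation. Higher and lower members were 7 and 1 of 24, 0 and 5 of 13, 1 and 6 of 37, and 2 and 0 of 13 (adjusted over the list alone, 10 and 1, 0 and 9, 2 and 15, 4 and 1). Over all lists, 84 of 94 member calls between doses at 24 h ended without at least 1 library. The call between doses at 24 h ended (adjusted p in parentheses) for BCL2 family genes as a list without library 8 or 9 (0.0812 and 0.0548).

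Solvent at 24 h against solvent at 16 h gave the background of time in culture. The YAP targets CYR61 (-0.76) and CTGF (-0.63) and the actin-binding TAGLN (-0.74) were lower at 24 h, and INSIG1 (0.43) and FDFT1 (0.25) higher (log2 changes). CCNB3 (1.99) was higher, and BCYRN1, RF02164, HIST2H2BD and HMGN1P38 were listed at 0 at 16 h and at 609.7 and 719, 94.2 and 109, 1.82 and 4.61 and 4.18 and 1.24 FPKM in the 2 libraries at 24 h (adjusted p = 0.000301, 0.0356, 0.0237 and 0.0444). RF00024 (-2.03), HYPK (-0.96) and MT-RNR1 (-0.94) were lower, and SNORD17 and RN7SL333P were listed at 0 at 24 h (22.5 and 8.85 and 2.37 and 1.77 FPKM at 16 h, adjusted p = 0.0226 and 0.00285). Between solvent groups, 756 of 13458 genes were called, 423 higher and 333 lower, 23 of them by at least 1 on the log2 scale. The split became 975 higher and 212 lower under rescaling to a common sum, 358 higher and 572 lower under median-of-ratios scaling and 376 higher and 576 lower under rescaling over nuclear genes. Without library 1, 2, 5, 6, 7, 8, 9, 10, 11 or 12 the count was 491, 491, 22, 89, 1448, 1446, 492, 491, 88 and 44 in turn. With no filter on low values the count was 326. Calls between solvent groups that ended (adjusted p in parentheses) were HIST2H2BD without library 5, 6 or 12 (0.0866 to 0.142), CTGF without library 5, 11 or 12 (0.0578 to 0.0910), CCNB3, FDFT1, INSIG1, SNORD17 and TAGLN without library 5, 6, 11 or 12 (0.0531 to 0.142). Likewise ended HMGN1P38 and RF02164 without library 3, 4, 5, 6, 9, 10, 11 or 12 (0.0520 to 0.166), HYPK without library 1, 2, 3, 4, 5, 6, 9, 10, 11 or 12 (0.0544 to 0.207).

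Between solvent groups, 10 lists were called. The 4 with the smallest adjusted p had medians at 24 h of YAP and TEAD targets -0.15, mitochondrially encoded genes -0.19, G2 and mitosis genes 0.09 and heat shock genes 0.11 (camera adjusted p = 0.000214, 0.000214, 0.00307 and 0.00307), with adjusted p = 0.157, 0.367, 0.367 and 0.367 with an estimated correlation. Higher and lower members were 0 and 5 of 17, 0 and 2 of 13, 5 and 1 of 44, and 4 and 0 of 14 (adjusted over the list alone, 0 and 7, 0 and 7, 11 and 2, 5 and 0). Over all lists, 70 of 73 member calls between solvent groups ended without at least 1 library.

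The difference of the 20 nM effect between 24 h and 16 h was tested for each gene. Mitotic genes such as PLK1 (-0.90), AURKA (-0.85) and CCNB1 (-0.78) had a lower effect at 24 h, and the replication genes CDC6 (0.96), RFC4 (0.81) and PCNA (0.66) a higher one (differences of log2 changes). Large positive differences by the rule were HIST1H2AM (2.17), HIST1H2BO (1.92) and PTBP2 (1.92), PTBP2 being a splicing regulator, and SNRPGP15 and RN7SL608P, listed at 0 in 1 and in several libraries (adjusted p = 0.0243 and 0.0345). Large negative differences were CCNB3 (-3.64) and SMARCA5-AS1 (-2.99), and BCYRN1, RF02164 and HMGN1P38, each listed at 0 in some groups (adjusted p = 7.69e-05, 0.0197 and 0.00843). For this difference, 1550 of 13458 genes were called, 950 higher and 600 lower, 70 of them by at least 1 on the log2 scale. The split became 346 higher and 2116 lower under rescaling to a common sum, 775 higher and 748 lower under median-of-ratios scaling and 625 higher and 934 lower under rescaling over nuclear genes. Without library 1, 2, 5, 6, 11 or 12 the count was 709, 740, 763, 995, 724 and 914 in turn. Under rescaling to a common sum the median difference of all genes shifted by -0.17, and with no filter on low values 1008 genes were called. Leaving out 1 library ended the call for the 20 nM difference (adjusted p in parentheses) for SNRPGP15 without library 2, 5 or 6 (0.0573 to 0.0832), HIST1H2BO without library 2, 5 or 12 (0.0651 to 0.0786), RF02164 without library 5, 6, 11 or 12 (0.0531 to 0.0601). Others that ended were SMARCA5-AS1 without library 1, 2, 5, 6 or 7 (0.0568 to 0.0853), HIST1H2AM without library 1, 2, 5, 6, 9, 10, 11 or 12 (0.0515 to 0.107), RN7SL608P without library 1, 2, 3, 4, 7, 8, 9, 10, 11 or 12 (0.0507 to 0.0932).

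List medians of the 20 nM difference were G2 and mitosis genes -0.47, replication genes 0.42 and histone genes 0.87. Camera adjusted p was 2.43e-15, 1.80e-16 and 2.03e-06, and 0.0206, 0.00797 and 0.0220 with an estimated correlation. Higher and lower members were 4 and 27 of 44, 25 and 0 of 37, and 9 and 0 of 22 (adjusted over the list alone, 5 and 30, 29 and 0, 12 and 0).

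For 100 nM, the effect at 24 h lay below that at 16 h for PLK1 (-0.82), AURKA (-0.77) and HSPA8 (-0.80) and above it for CCNE2 (1.95), CDC6 (1.046) and DUSP6 (1.12). Large positive differences by the rule were HIST1H2BO (2.75), HIST1H2BK (2.45) and HIST2H2AA4 (2.21), and RPS26P6 and SNORD17, listed at 0 in some groups (adjusted p = 9.09e-05 and 0.0443). The largest negative ones were GAS2L3 (-1.12), SHD (-1.10), PRDM10 (-1.04) and SERPING1 (-1.02), GAS2L3 being a linker of actin and microtubules, and BCYRN1, listed at 0 in solvent at 16 h (adjusted p = 0.000665). For the higher dose, 1368 of 13458 genes were called, 790 higher and 578 lower, 81 of them by at least 1 on the log2 scale. The split became 548 higher and 903 lower under rescaling to a common sum and 581 higher and 875 lower under rescaling over nuclear genes. Without library 4, 5, 6, 9, 10, 11 or 12 the count was 733, 694, 725, 630, 637, 716 and 650 in turn. The call for the 100 nM difference ended (adjusted p in parentheses) for SERPING1 without library 4, 5, 9, 10 or 12 (0.0562 to 0.0724), SHD without library 3, 4, 5, 6, 10, 11 or 12 (0.0533 to 0.0728), PRDM10 without library 3, 4, 5, 6, 9, 10, 11 or 12 (0.0671 to 0.131). It also ended for SNORD17 without library 3, 4, 5, 6, 7, 8, 9, 10, 11 or 12 (0.0515 to 0.131).

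List medians of the 100 nM difference were G2 and mitosis genes -0.54, replication genes 0.39 and histone genes 1.43. Camera adjusted p was 1.04e-22, 7.59e-17 and 3.44e-10, and 0.00644 for each with an estimated correlation. Higher and lower members were 2 and 34 of 44, 22 and 0 of 37, and 13 and 0 of 22 (adjusted over the list alone, 4 and 37, 27 and 0, 15 and 0).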

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

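Tests of the solvent change with time, of the scaling between libraries, of shared reads and of the shortest genes were chosen after the result was seen. The next 4 paragraphs give differences of log2 changes (24 h minus 16 h) of named genes and lists that passed the limma or camera test of that difference, and the list members among them were chosen after their values were seen.

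The 20 nM effect differed between 24 h and 16 h, by the limma test of the difference itself, in 1550 genes. Of these genes, the effect was higher at 24 h for HIST1H2AM (2.17), HIST1H2BO (1.92), PTBP2 (1.92), HIST1H4H (1.78), HIST1H1C (1.54), RPS3AP26 (1.49), MAPK15 (1.48), HIST2H2AA4 (1.45), HIST1H2BK (1.24), FBXO5 (1.19), RBM23 (1.11), CTGF (1.09), HIST1H2BD (1.07) and IFIT2 (1.03). Higher at 24 h too were CDC6 (0.96), MT-ATP8 (0.93), HIST2H2BE (0.90), HIST1H2AC (0.85), RFC4 (0.81), CDK1 (0.81), SUCNR1 (0.79), DUSP6 (0.72), PCNA (0.66), TOP2A (0.65), NUSAP1 (0.64), ORC1 (0.62), MCM5 (0.59) and TUBB (0.59). Smaller positive differences were those of MT-ND6 (0.55), DHRS3 (0.53), CCNE2 (0.52), IFIT1 (0.50), MYC (0.37), UBE2C (0.31), EPCAM (0.31), ASB8 (0.29), MCL1 (0.28), TUBA1C (0.28), PMAIP1 (0.27) and TUBA1B (0.24). It was lower at 24 h for CCNB3 (-3.64), SMARCA5-AS1 (-2.99), TMEM265 (-1.54), SHD (-1.28), POLR2L (-0.92), GAS2L3 (-0.91), PLK1 (-0.90), HSPA1A (-0.88) and AURKA (-0.85). Lower effects were also those of KIF20A (-0.84), CCNB1 (-0.78), SLC7A5P2 (-0.72), SDC1 (-0.69), CDC20 (-0.69), HSPA8 (-0.53), HSPA1B (-0.38), DNAJB1 (-0.24) and FDFT1 (-0.22). Listed at 0 in at least 1 library, and so without a fold, were SNRPGP15, RN7SL608P, BCYRN1, RF02164, HMGN1P38 and RN7SL333P. Their adjusted p was 0.0243, 0.0345, 7.69e-05, 0.0197, 0.00843 and 0.00271 in turn. Of 64 such genes, 26 lost the limma call without at least 1 library, and leaving out library 1 to 12 in turn ended 20, 20, 3, 3, 17, 15, 6, 6, 6, 6, 17 and 13 calls (adjusted p = 0.0502 to 0.143).

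Camera called a difference of medians for histones (0.87), G2 and mitosis (-0.47), DNA replication (0.42), mitochondrially encoded genes (0.37) and interferon response (0.36), with adjusted p = 0.0220, 0.0206, 0.00797, 0.258 and 0.0349 with an estimated correlation, in that order. Next were ERK output (0.26), heat shock (-0.25), immediate early genes (0.20), SRF and actin (-0.19) and cholesterol synthesis (-0.17), with adjusted p = 0.221, 0.0790, 0.380, 0.134 and 0.221 with an estimated correlation, in that order. The smallest were autophagy (0.15), microtubule-associated proteins (-0.13) and the unfolded protein response (-0.0459), with adjusted p = 0.221, 0.113 and 0.380 with an estimated correlation, in that order. The call of a list ended without a library (adjusted p in parentheses) for the unfolded protein response without library 6 (0.101) and autophagy without library 1 (0.0580). Under rescaling to a common sum the autophagy difference at 20 nM turned to -0.01, or 0.13 relative to all genes.

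The 100 nM effect differed between 24 h and 16 h, by the limma test of the difference itself, in 1368 genes. Higher effects at 24 h were those of HIST1H2BO (2.75), HIST1H2BK (2.45), HIST2H2AA4 (2.21), HIST1H2AM (2.03), CCNE2 (1.95), HIST1H1C (1.83), HIST1H2AC (1.82), HIST1H2BC (1.69), HIST1H2BD (1.66), HIST1H4H (1.63), HIST2H2BE (1.59), IFIT2 (1.52) and FBXO5 (1.502). The effect was also higher for PTBP2 (1.47), NR4A2 (1.27), CTGF (1.24), MAPK15 (1.18), DUSP6 (1.12), CDC6 (1.046), OASL (1.01), FOSB (0.97), RBM23 (0.92), SNAI2 (0.90), STC2 (0.81), ORC1 (0.68) and MYC (0.62). Further positive differences were those of IFIT1 (0.59), PCNA (0.57), HES1 (0.56), MCM5 (0.56), EGR1 (0.50), RFC4 (0.49), CDK1 (0.45), SOX4 (0.43), CYR61 (0.37), PMAIP1 (0.32), FOSL1 (0.30) and TUBB (0.28). Lower effects at 24 h were those of GAS2L3 (-1.12), SHD (-1.10), PRDM10 (-1.04), SERPING1 (-1.02), H19 (-0.84), PLK1 (-0.82), HSPA8 (-0.80), FAM83D (-0.79), HSPA1B (-0.77), AURKA (-0.77), HSPA1A (-0.75), KIF20A (-0.72), DNAJB1 (-0.71) and P4HA2 (-0.69). The effect was lower as well for OLFM2 (-0.64), GMPR (-0.63), CCNB1 (-0.62), NEURL1B (-0.56), INSIG1 (-0.54), AURKB (-0.50), FDFT1 (-0.48), FLOT2 (-0.48), SDC1 (-0.47), CKAP5 (-0.44), CKS1B (-0.34), TRIOBP (-0.33), TUBB4B (-0.30) and BEX3 (-0.26). Listed at 0 in at least 1 library, and so without a fold, were RPS26P6, SNORD17, BCYRN1 and RN7SL333P. Their adjusted p was 9.09e-05, 0.0443, 0.000665 and 0.00266 in turn. Of 70 such genes, 25 lost the limma call without at least 1 library, and leaving out library 1 to 12 in turn ended 5, 5, 18, 19, 23, 20, 1, 1, 19, 21, 19 and 22 calls (adjusted p = 0.0506 to 0.150).

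Camera called a difference of medians for histones (1.43), immediate early genes (0.54), G2 and mitosis (-0.54), DNA replication (0.39) and interferon response (0.31), with adjusted p = 0.00644, 0.0576, 0.00644, 0.00644 and 0.0457 with an estimated correlation, in that order. Next were ERK output (0.30), cholesterol synthesis (-0.24), heat shock (-0.22), microtubule-associated proteins (-0.17) and autophagy (0.14), with adjusted p = 0.0576, 0.0576, 0.0337, 0.0556 and 0.222 with an estimated correlation, in that order. The smallest were the ATF4 response (0.14), oxidative phosphorylation (0.12), cytosolic ribosomal proteins (0.0881) and SRF and actin (-0.0731), with adjusted p = 0.222, 0.598, 0.611 and 0.222 with an estimated correlation, in that order. The call of a list ended without a library (adjusted p in parentheses) for autophagy without library 3 or 5 (0.136 and 0.0731), cytosolic ribosomal proteins without library 4, 5, 9 or 11 (0.0692 to 0.157) and oxidative phosphorylation without library 4 or 5 (0.157 and 0.0621).

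Of 22 replication-dependent histone genes, 15 at 20 nM and 12 at 100 nM were higher at 24 h (camera adjusted p = 1.16e-10 and 2.78e-08, 0.0157 and 0.0284 with an estimated correlation). Other protein-coding genes of the same transcript lengths (6720 genes) had a median change of 0.0205 at 100 nM against 1.003 for the list, and the 29 shortest 0.0553, which argues against gene length. FPKM summed over 90 HIST genes rose by a log2 ratio of 2.63 at 100 nM and 2.5005 at 20 nM. This sum can change if reads move among copies of unlike length, so it cannot exclude that. Also open are a change in histone mRNA with the drug or in its capture by poly(A) selection. These hypotheses may look alike and were not tested.

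G2 and mitosis genes had a higher median than solvent at 16 h and a lower one at 24 h. Solvent alone changed the list by 0.0884 between times, against a difference of -0.536 at 100 nM. After a transcript length trend was subtracted the difference was -0.565, and under 3 scalings, with nothing subtracted, it lay between -0.661 and -0.506 over both doses, at least 1.011 of its size as deposited. These values argue against solvent time, length and those scalings as the cause. A change of cell cycle position with time in drug may account for it, a hypothesis that these libraries do not test.

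Of 29 genes listed at 0 in both libraries of a group and at 2 FPKM or more in both of another, 28 had an annotated transcript length, and 60.7% of these had no annotated transcript of 300 bases or more, against 0.360% of all genes at that level. Pseudogenes and small RNAs made up 51.7% of the 29, against 2.98%. In 10 of the 29 a single drug group alone was at 0. Short transcripts or reads shared with copies may account for many of these zeros, BCYRN1 among them. Drug, dose and time stay open, as untested.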

How the results depend on the processing

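Rescaling over nuclear genes and the restriction to protein-coding genes were chosen after the data were seen. No paired analysis was possible because the columns lack the sample number of the labels. The fit of one time point's libraries does not apply to comparisons across times. The 9 counts of calls, the 5 counts of shared calls and the 4 correlations stayed within 1.5 times (counts) or 1 jackknife standard error over libraries (correlations), outside leave-one-out, except as follows, and the cause was not tested where none is named. Between doses at 16 h, calls numbered 28 with a constant prior and 18 with the libraries of that time alone, a fit of fewer libraries. Between doses at 24 h they numbered 334 with no filter on low values, 411 with a constant prior and 10 with the libraries of that time alone. Between solvent groups they numbered 326 with no filter and 1187 under rescaling to a common sum, and for the 20 nM difference between times 1008 and 2462. The correlation between times at 20 nM was 0.37 over protein-coding genes, and at 100 nM it was 0.29 with a pseudocount of 0.1, 0.33 with no filter and 0.48 over protein-coding genes. Gene lists called by camera numbered 8, 10, 13, 10, 10, 8, 10, 13 and 14 over the 9 comparisons (20 nM and 100 nM at 16 h, then at 24 h, doses at 16 h and 24 h, solvent, differences at 20 nM and 100 nM) and 1, 1, 7, 1, 1, 0, 0, 4 and 5 with an estimated correlation. By fry, which tests only whether a list moves, they numbered 15, 21, 20 and 21 in the drug comparisons and 3 between doses at 24 h, and rescaling to a common sum left 6 at 100 nM and 16 h. MYC at 20 nM and 24 h turned from 0.18 to -0.0117 under rescaling to a common sum (limma adjusted p = 0.862). Of 630 calls of genes named in the text, 120 were lost with no filter, 50 with a constant prior, 41 under rescaling to a common sum, 20 over nuclear genes, 15 under median-of-ratios scaling and 15 and 6 with pseudocounts of 0.1 and 0.5. With the libraries of 1 time alone 84 of 460 were lost, at 5 FPKM in 2 libraries 1 of 552 and over protein-coding genes 0 of 554, and no other named call turned.

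Leaving out each library in turn left an arm with 1 library, assumed to vary like the other groups. In that order of comparisons, calls ranged from 1041 (without library 1) to 2778 (7), 1782 (without library 5) to 3621 (7), 2153 (without library 11) to 3769 (3), 2757 (without library 9) to 5009 (7), 15 (without library 2) to 65 (7), 41 (without library 9) to 1526 (7), 22 (without library 5) to 1448 (7), 709 (without library 1) to 1759 (7) and 630 (without library 9) to 1792 (8). Shared calls ranged from 916 (without library 5) to 2197 (8), 1567 (without library 11) to 2690 (8), 491 (without library 1) to 1053 (8), 1003 (without library 5) to 1922 (7) and 429 (without library 5) to 840 (8) for the doses at 16 h and 24 h, the times at 20 nM and 100 nM, and all 4 comparisons. The correlations ranged from 0.69 (without library 3) to 0.81 (6), 0.64 (without library 7) to 0.76 (11), 0.14 (without library 1) to 0.21 (2) and 0.34 (without library 6) to 0.38 (2), and lists called from 7 (without library 6) to 10 (5), 6 (without library 3) to 10 (1), 11 (without library 7) to 14 (8), 9 (without library 5) to 10 (1), 9 (without library 1) to 12 (4), 4 (without library 8) to 9 (7), 6 (without library 6) to 9 (1), 12 (without library 1) to 15 (8) and 11 (without library 5) to 14 (1). Of 1617 calls of list members, 1356 kept call and direction under rescaling to a common sum, 241 lost the call and 20 turned, and 0 turned under the other settings tried for them (pseudocount, filter, prior, other scalings, protein-coding genes, leave-one-out), where between 1268 of 1617 (no filter) and 1617 of 1617 (protein-coding genes) kept the call outside leave-one-out. Over the 9 comparisons in that order, 109 of 226, 96 of 259, 113 of 297, 121 of 331, 7 of 8, 84 of 94, 70 of 73, 80 of 163 and 67 of 166 such calls ended without at least 1 library. A list uncalled in both settings was counted as unchanged whatever its sign. Under rescaling to a common sum 6 of 96 called list medians changed sign, over nuclear genes 1 and under median-of-ratios scaling 0. Depth is unknown, so no floor could be set for values listed at 0.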

Other observations

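The genes below, whose changes with the drug stand nowhere above, were picked after their values were seen. SNAI2, a repressor of epithelial genes, rose in the 4 drug comparisons, by 0.85 and 0.68 at 16 h (20 nM and 100 nM) and by 1.26 and 1.58 at 24 h on the log2 scale. The epithelial surface protein EPCAM was higher at 24 h (0.37 and 0.17), with values at 16 h of 0.06 and 0.00 that did not pass. Of the fixed list of epithelial genes, more fell than rose at 100 nM and 24 h, and camera called that list in no drug comparison. The mesenchymal filament gene VIM was lower at 100 nM and 24 h (-0.17), and its other changes were -0.06, -0.13 and -0.12. DDIT3, a stress-induced factor, rose by 0.63, 0.61, 0.40 and 0.64 in the same order. All are limma results with Benjamini-Hochberg adjustment, each from 2 libraries per group. The call at 20 nM and 24 h ended (adjusted p in parentheses) for DDIT3 without library 12 (0.0544). Calls at 100 nM and 24 h that ended (adjusted p in parentheses) were EPCAM without library 9 or 11 (0.0544 to 0.0587), VIM without library 9, 10, 11 or 12 (0.0578 to 0.0954).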
